A study of Danio rerio with 45 samples.

How the data were processed

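The series measured whole zebrafish embryos (Danio rerio, strain AB/PS) by stranded RNA sequencing of total RNA after removal of ribosomal RNA, on a HiSeq 2000, per the labels' protocols. Wild-type embryos (WT) and embryos injected with a morpholino against rad21 (Rad21 MO) or ctcf (CTCF MO) were collected at 5 stages in hours post fertilisation (hpf): 2.5 and 3.3 hpf, 4.5 and 5.3 hpf, and 10 hpf. Each of the 15 groups held 3 libraries, each from 100 pooled embryos matched in stage by eye. Groups were taken from the sample titles. For 1 Rad21 MO library titled 3.3 hpf the age label says 4.5 hpf, and for 1 titled 4.5 hpf it says 3.3 hpf. The table's columns name the group and a column number, not the replicate letter of the titles, so these libraries could not be matched to columns and each column kept the stage its name gives.

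The main table holds FPKM (fragments per kilobase of transcript per 1e+06 mapped fragments) per gene and library, as deposited by the authors. Per the submitters' processing notes, TopHat2 2.0.9, Cufflinks 2.2.0 and Cuffdiff were used with the zebrafish genome Zv9 (danRer7). The version of Cuffdiff and any scaling between libraries are not given in the sources used here. Separate tables deposited by the authors hold, for their own comparisons, group FPKM values, a log2 fold change, a test statistic (a score), a p-value and a q-value, with only the genes they marked as significant. Coordinates are those of the authors' file on Zv9, whose counting from 0 or 1 is not stated. The table lists 31966 genes, of which 498 are merged loci that carry several symbols. For 19 symbols a spreadsheet had turned the name into a date. FPKM depends on the annotated length and on what else the library holds, so a rise of abundant RNAs lowers every other value. FPKM sums ranged from 676000 to 1816000, and small non-coding RNAs made up 14.9% to 34.6% of them. Near-identical copies, such as histone genes, and overlapping loci share reads, so their separate values are uncertain.

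FPKM gives no read totals. Steps between low values gave a relative depth, as the commonest ratio of a low gene's values between libraries, and this spanned 2.48-fold from the shallowest to the deepest library. That ratio was shared by 13.8% to 33.2% of the low genes, too few to recover whole reads, so no count test was run. An exact 0 can be a failed estimate, and genes with libraries at 0 are described as listed at 0.

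Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, moderated two-sided test with a mean-variance trend, Benjamini-Hochberg adjustment, call at adjusted p under 0.05). A gene was tested if at least 3 libraries of the fit reached 1 FPKM. All fold changes are on this log2(FPKM + 1) scale, which understates changes of low genes. In comparisons of a knockdown, rose and fell mean above and below WT of the same stage, not a change over time. Each stage was fitted on its 9 libraries, the WT course on the 15 WT libraries, and differences of an effect between stages on all 45. Tables were handled with the R package data.table (version 1.17.8), and plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

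Fixed gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. They cover subunits and regulators of cohesin with ctcf, early zygotic genes, oocyte genes, regulators of genome activation, Nodal and mesendoderm, BMP and ventral, FGF and Wnt, enveloping layer, yolk syncytial layer, germline, neural, paraxial mesoderm, hox, p53 targets, cell cycle, ribosomal proteins, ribosome biogenesis, histones, mitochondrially encoded transcripts, clustered protocadherins, genes linked to cohesin in earlier work, miR-430 copies, heat and stress response, ovarian somatic cells and tissues of later stages. The last pair marks other cell types. In addition, a maternal and a zygotic class were built from WT libraries of other stages than the one compared. For 3.3, 4.5 and 5.3 hpf they hold genes that fell or rose at least 4-fold in WT from 2.5 to 10 hpf, and for 2.5 and 10 hpf from 3.3 to 5.3 hpf. A position along WT development was computed by projecting each library on the line from the mean WT profile of the stage before (0) to that of the stage after (1), over genes that differ at least 2-fold between them, and was compared by an exact two-sided permutation test, which cannot give a p under 0.1 with 3 against 3 libraries. At each stage the overlap of calls between the knockdowns was set beside 100 simulations of unchanged groups that share the WT libraries.

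Named genes follow a rule: adjusted p under 0.05, all 3 libraries of a group above or below those of the other, a mean of at least 5 FPKM in the higher group and a gene symbol rather than a clone name. The 10 largest rises and 10 largest falls per comparison and up to 4 members of each list with the smallest adjusted p were eligible, and rad21a, rad21b, ctcf, pou5f1, nanog, sox19b and the members of a described early zygotic list always. Groups, lists, tests, this rule and the alternative settings named next were chosen before the data were examined. They were a pseudocount of 0.1, no filter, rescaling of each library to a sum of 1e+06, quantile normalization, 1 fit of all 45 libraries, at least 2-fold changes, fry and the estimated correlation, and leaving out each library. A block by column number and the exchange or removal of 1 Rad21 MO library each of 3.3 and 4.5 hpf were added after the data had been seen.

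The fits were tested on simulated data with 200 changed genes per stage. At 4.5 hpf, among 14910 simulated genes, 62 of 66 genes changed 4-fold, 35 of 67 changed 2-fold and 6 of 67 changed 1.5-fold were recovered with 8 false calls. At 10 hpf, among 16419 genes, 59 of 66, 37 of 67 and 6 of 67 were recovered with 7 false calls. In 10 simulated sets with no effect, the fit of 45 libraries called between 0 and 61 genes whose effect differed between adjacent stages. Its mean was 37.2 genes for Rad21 MO and 43.1 for CTCF MO from 5.3 to 10 hpf, so small counts from this fit carry little weight.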

Results

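Zebrafish embryos were followed from 2.5 to 10 hours post fertilisation (hpf), a span that takes in the activation of the embryo's own genome and gastrulation. Transcript levels of WT embryos were compared with those of embryos injected with a morpholino, an antisense oligomer that blocks translation or splicing of its target RNA. One morpholino targeted rad21, which encodes a subunit of the chromosome-holding cohesin ring, and the other ctcf, which encodes a DNA-binding protein that helps to position cohesin. The question put by the design was whether loss of either protein changes the transcripts present before, during and after genome activation. There were 3 libraries for each of the 3 treatments at each of the 5 stages, 45 in all, and each library came from 100 pooled embryos. Labels do not say that pools came from separate clutches or whether WT embryos were injected, so p-values measure the spread between these pools, which may be technical. Between 12790 and 15830 genes reached 1 FPKM in a library, and replicate libraries correlated across genes with r from 0.940 to 0.976. The FPKM tables give no read totals, and relative depth spanned 2.48-fold between libraries.

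The targeted transcripts were read first. In WT, rad21a (Zv9 chromosome 16, 51486520 to 51734308) stood at 60.3 ± 2.94 FPKM at 2.5 hpf and 203 ± 10.4 at 5.3 hpf (SD, n = 3). There ctcf (chromosome 18, 22066702 to 22074092) was at 120.4 ± 4.66 and 496 ± 21.96. In Rad21 MO embryos rad21a was 63.9 ± 1.98 FPKM at 2.5 hpf and 77.0 ± 3.56 at 3.3 hpf, close to WT with 73.0 ± 4.31 at 3.3 hpf. It was below WT at 4.5 hpf, at 100.5 ± 10.3 FPKM against 143 ± 13.6 (log2 change -0.51, SE 0.12, adjusted p = 0.0194). At 5.3 hpf it was at 154 ± 10.5, again below WT (log2 change -0.40, SE 0.084, adjusted p = 0.0101). It stood at 183 ± 10.7 against 170 ± 31.7 at 10 hpf (adjusted p = 0.719). In CTCF MO embryos ctcf was 119.5 ± 5.31 FPKM at 2.5 hpf, 135 ± 7.17 at 3.3 hpf and 260 ± 55.3 against 399 ± 46.2 at 4.5 hpf (adjusted p = 0.196). It was below WT at 5.3 hpf, at 237 ± 3.39 against 496 ± 21.96 (log2 change -1.06, SE 0.077, adjusted p = 0.000388), and was 155 ± 13.1 against 150 ± 6.66 at 10 hpf (adjusted p = 0.999). In each knockdown the other transcript was also below WT. From 3.3 to 5.3 hpf both transcripts still rose in each knockdown, but less than in WT. Levels of ctcf were below WT in Rad21 MO embryos at 4.5 hpf (log2 change -0.70, adjusted p = 0.0273), 5.3 hpf (-0.59, adjusted p = 0.00148) and 10 hpf (-0.64, adjusted p = 0.0177). Those of rad21a were below WT in CTCF MO embryos at 5.3 hpf (-0.35, adjusted p = 0.0332). The second rad21 copy, rad21b (chromosome 19, 45574454 to 45597610), was close to 0 before 10 hpf and reached 1.43 ± 0.653 FPKM in WT, 1.13 ± 0.171 in Rad21 MO and 0.741 ± 0.396 in CTCF MO embryos at 10 hpf. A morpholino need not lower its target's RNA, so these levels do not measure protein loss. The call of ctcf in CTCF MO embryos at 5.3 hpf held in every alternative tried. The calls of rad21a and of ctcf in Rad21 MO embryos ended when libraries were rescaled to 1e+06. Calls of these genes at 4.5 and 10 hpf and that of rad21a in CTCF MO embryos also ended without single libraries of either group.

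**Figure D1:**
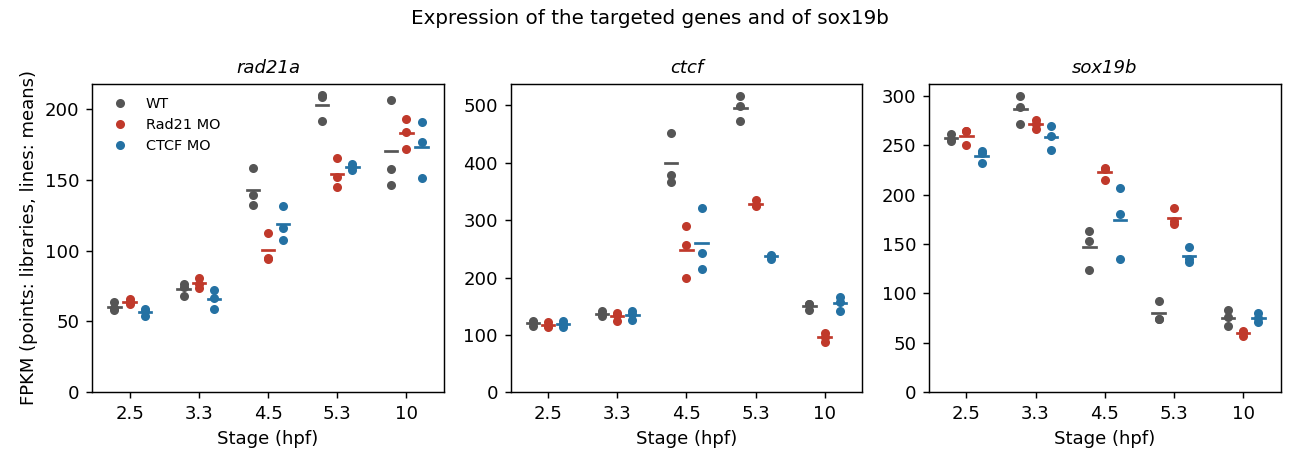
FPKM (vertical axes) of rad21a, ctcf and sox19b in each library (points) with group means (short lines) against stage in hpf, for WT, Rad21 MO and CTCF MO. At 5.3 hpf ctcf is at 237 ± 3.39 in CTCF MO, 329 ± 4.80 in Rad21 MO and 496 ± 21.96 in WT libraries (SD, n = 3).

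WT embryos replaced maternal by zygotic transcripts along this course. Between 2.5 and 3.3 hpf the zygotic zinc finger gene blf (chromosome 22, 10027156 to 10033842) rose from 3.603 ± 0.842 to 62.7 ± 11.1 FPKM (log2 change 3.79, SE 0.23, adjusted p = 1.98e-07). By 4.5 hpf the enveloping layer keratin krt4 (chromosome 6, 39239361 to 39243891) had risen from 1.29 ± 0.84 to 342 ± 103 FPKM (log2 change 7.26, adjusted p = 5.05e-10). Levels of btg4 (chromosome 5, 59273721 to 59275804), an adaptor in the removal of maternal mRNA, had by then fallen from 302 ± 6.82 to 32.6 ± 6.19 FPKM (log2 change -3.19, adjusted p = 9.49e-07). The neural gene sox2 then rose from 1.98 ± 2.55 to 31.4 ± 17.2 FPKM by 5.3 hpf (log2 change 3.602, adjusted p = 0.000533). By 10 hpf the intestinal fatty acid binding gene fabp2 reached 703 ± 158 FPKM (log2 change 8.91, adjusted p = 5.32e-13). The pluripotency genes pou5f1 and nanog fell to 4.83 ± 0.382 and 4.19 ± 2.57 FPKM (log2 changes -6.88 and -6.70). limma called 428 genes between 2.5 and 3.3 hpf (358 higher, 70 lower), and 8119 up to 4.5 hpf (4398 higher, 3721 lower). It called 4242 up to 5.3 hpf (2462 higher, 1780 lower) and 11988 up to 10 hpf (6560 higher, 5428 lower), of 17410 tested. These splits hang on the scaling. Rescaled to 1e+06, 2228 genes were higher and 7098 lower between 3.3 and 4.5 hpf, and 865 and 3549 between 4.5 and 5.3 hpf. The median of all genes was then -0.35 and -0.18, against 0.032 and 0.021 before. Quantile normalization gave 408 and 158 between 2.5 and 3.3 hpf and 1671 and 1912 between 4.5 and 5.3 hpf, and put the median at -0.11 between 5.3 and 10 hpf, against 0.073 before. The count between 4.5 and 5.3 hpf was 2564 without replicate 0 of 4.5 hpf, 2651 without replicate 1 of 5.3 hpf and 2784 without replicate 0 of 5.3 hpf.

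Before genome activation, at 2.5 hpf, no single gene stood apart from WT in either knockdown. limma called 0 of 13595 genes in Rad21 MO and 0 in CTCF MO embryos, with 544 and 1140 genes at an unadjusted p under 0.05. In comparison, the authors' deposited table, made with Cuffdiff, lists 70 and 164. The libraries of morpholino and WT did not overlap for 9.44% and 13.0% of genes, where chance gives 10%. As a group, 28 measured early zygotic genes had a median log2 change of 0.32 in Rad21 MO embryos. Of these 22 lay above 0, with none called over all genes or adjusted over the list alone (camera adjusted p = 0.000349, adjusted p = 0.641 with an estimated correlation). The same genes had a median of -0.23 in CTCF MO embryos, 6 of them above 0 and none called (camera adjusted p = 0.119). There 48 histone genes had a median of -0.17 (-0.034 under quantile normalization) with 0 called, 1 lower adjusted over the list alone (camera adjusted p = 0.000965, adjusted p = 0.813 with an estimated correlation). Without Rad21 MO replicate 2 limma called 1 gene in that comparison, and in CTCF MO embryos 2 genes without replicate 0 and 5 without replicate 2. Rescaling to 1e+06 put the median of all genes at 0.14 in Rad21 MO embryos, against 0.011 before.

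At 3.3 hpf early zygotic genes lay above WT in both knockdowns. Of 48 measured members 46 had a higher level in Rad21 MO embryos (median log2 change 0.64). Over all genes 2 rose, and 22 adjusted over the list alone (camera adjusted p = 1.97e-26, adjusted p = 0.123 with an estimated correlation). Those called were chd (chromosome 15, 46135904 to 46173284), a secreted BMP antagonist, at 5.35 ± 0.844 against 1.58 ± 0.549 FPKM (SD, n = 3; log2 change 1.31, SE 0.19, adjusted p = 0.0426), and cyp26a1. The latter (chromosome 12, 9708962 to 9712555), which degrades retinoic acid, was at 54.7 ± 7.80 against 27.7 ± 5.07 FPKM (log2 change 0.96, SE 0.14, adjusted p = 0.0426). In CTCF MO embryos 44 of the 48 lay above WT (median 0.56). Here 0 were called over all genes and 18 adjusted over the list alone (camera adjusted p = 1.21e-15, adjusted p = 0.201 with an estimated correlation). The lists overlap: 42 of 59 matched early zygotic genes and 19 of 28 matched Nodal and mesendoderm genes are also on other lists. Nodal and mesendoderm genes, which are thus no independent group, did likewise. Their median was 0.53 in Rad21 MO embryos (1 of 19 rose, 7 adjusted over the list alone, camera adjusted p = 5.89e-11, adjusted p = 0.132 with an estimated correlation). It was 0.59 in CTCF MO embryos (0 called, 1 adjusted over the list alone, camera adjusted p = 1.12e-06, adjusted p = 0.201 with an estimated correlation). The rise was not limited to these lists. The zygotic class had medians of 0.104 in Rad21 MO and 0.108 in CTCF MO embryos (camera adjusted p = 9.83e-06 and 1.13e-05, both 0.174 with an estimated correlation). Enveloping layer genes had medians of 0.42 and 0.47 and neural genes of 0.34 and 0.35, while hox genes had -0.27 and -0.15. Another gene that rose in Rad21 MO embryos was pef1 (chromosome 19, 38669387 to 38683108) at 19.3 ± 0.973 against 7.21 ± 0.429 FPKM (log2 change 1.31, SE 0.12, adjusted p = 0.00466). In CTCF MO embryos the ubiquitin-conjugating enzyme gene UBE2U (chromosome 6, 55261893 to 55289106) stood at 171 ± 4.29 against 67.8 ± 11.2 and the G protein gene gnai2l (chromosome 11, 35635059 to 35755762) at 63.3 ± 3.08 against 30.3 ± 3.04 FPKM (log2 changes 1.34 and 1.04, both adjusted p = 0.00271).

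Over all 14051 genes tested at 3.3 hpf, 24 changed in Rad21 MO embryos (23 higher, 1 lower) and 8 in CTCF MO embryos (7 higher, 1 lower). Levels of morpholino and WT libraries did not overlap for 15.1% and 16.6% of genes, where chance gives 10%. The calls of chd, cyp26a1 and pef1 ended without single libraries. The Rad21 MO count was 2 without WT replicate 1, 2 without Rad21 MO replicate 2, 6 without Rad21 MO replicate 0 and 8 without WT replicate 0 or 2. In CTCF MO embryos it was 4 without WT replicate 1 or CTCF MO replicate 0 and 21 without CTCF MO replicate 2. The calls of gnai2l and UBE2U held in each of these runs, the latter ending only in the fit of all 45 libraries. The small nucleolar RNA gene SNORA32 was listed at 0 in the WT libraries and at 66.5, 25.4 and 67.9 FPKM in Rad21 MO and 81.3, 33.8 and 35.96 in CTCF MO libraries. The only gene lower in both, si:dkey-43b14.3, was at 2027, 1711 and 3968 FPKM in WT and at 0 in all 6 morpholino libraries. These names lie outside the naming rule and were chosen after their values were seen.

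At 4.5 hpf Rad21 MO embryos held more of many transcripts that the egg supplies. Levels of btg4 were 213 ± 60.9 FPKM against 32.6 ± 6.19 in WT (SD, n = 3; log2 change 2.65, SE 0.25, adjusted p = 0.00148). Those of buc (chromosome 2, 28022980 to 28027100), which organises the Balbiani body of the oocyte, were 201 ± 29.8 against 60.6 ± 12.1 (log2 change 1.72, SE 0.19, adjusted p = 0.00185). Levels of the metallothionein gene mt2 (chromosome 18, 17193794 to 17195147) were 399 ± 80.3 against 65.1 ± 6.53 (log2 change 2.58, SE 0.23, adjusted p = 0.00148). The germline RNA-binding gene dazl (chromosome 19, 20871400 to 20886168) rose to 107 ± 20.1 against 37.9 ± 5.13 FPKM, and the germ granule gene tdrd6 (chromosome 20, 35470063 to 35484057) to 59.7 ± 4.74 against 17.5 ± 3.08 (log2 changes 1.47 and 1.73, adjusted p = 0.00728 and 0.00148). Of 12 germline genes measured 6 rose and 0 fell, 7 and 2 adjusted over the list alone (median 0.55, camera adjusted p = 0.00284, adjusted p = 0.285 with an estimated correlation). Of 29 oocyte genes 10 rose and 1 fell, 12 and 2 adjusted over the list alone (median 0.068, camera adjusted p = 0.0097, adjusted p = 0.674 with an estimated correlation). The maternal class as a whole had a median log2 change of 0.42, with 483 of 1409 genes higher and 32 lower (camera adjusted p = 1.92e-18, adjusted p = 0.174 with an estimated correlation).

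Zygotic transcripts lay lower in the same embryos. The splicing regulator ptbp1a (chromosome 2, 26436470 to 26448682) stood at 15.1 ± 1.95 FPKM against 48.6 ± 17.0 in WT (log2 change -1.57, SE 0.31, adjusted p = 0.0102). The cold-inducible RNA-binding gene cirbp (chromosome 22, 18766096 to 18770361) stood at 512 ± 31.0 against 1436 ± 205 (log2 change -1.48, SE 0.20, adjusted p = 0.00323). The BMP ligand gene bmp7a (chromosome 11, 7194746 to 7226326) was at 15.4 ± 0.705 against 37.7 ± 1.79 (log2 change -1.23) and the epithelial transcription factor gene grhl1 (chromosome 17, 32594438 to 32632150) at 15.6 ± 0.394 against 39.3 ± 6.97 (log2 change -1.27, SE 0.15, adjusted p = 0.00227). In the zygotic class 9 of 2060 genes rose and 369 fell (median -0.43, camera adjusted p = 3.85e-13, adjusted p = 0.348 with an estimated correlation). Of 18 enveloping layer genes 0 rose and 3 fell, 8 adjusted over the list alone (median -0.69, camera adjusted p = 0.000655, adjusted p = 0.674 with an estimated correlation). Of 56 early zygotic genes 3 rose and 9 fell, the same numbers adjusted over the list alone (median -0.32, camera adjusted p = 0.0367, adjusted p = 0.793 with an estimated correlation). One of those that fell was blf, at 256 ± 9.29 against 461 ± 50.5 FPKM (log2 change -0.84, adjusted p = 0.00399). Among activators of the zygotic genome, pou5f1 fell to 308 ± 53.9 against 464 ± 87.9 FPKM (log2 change -0.59, adjusted p = 0.0415). In contrast sox19b (chromosome 7, 27620450 to 27623815) rose to 223 ± 6.65 against 147 ± 20.2 (log2 change 0.61, adjusted p = 0.028) and nanog stood at 632 against 773 (log2 change -0.29, adjusted p = 0.1).

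Histone, ribosomal protein and ribosome biogenesis genes were also lower as groups in the deposited values. Of 49 histone genes 34 fell and 0 rose, 39 adjusted over the list alone (median -0.69, camera adjusted p = 2.91e-13, adjusted p = 0.285 with an estimated correlation). An example was HIST2H2AB (2 of 30) at 563 ± 75.5 against 1351 ± 96.2 FPKM, but copies share reads and are uncertain singly. Of 70 ribosomal protein genes 16 fell and 0 rose, 39 adjusted over the list alone (median -0.56, camera adjusted p = 2.85e-11, adjusted p = 0.674 with an estimated correlation), with rpl3 (chromosome 3, 30018331 to 30022483) at 199.8 ± 10.8 against 317 ± 30.5 FPKM. Of 58 ribosome biogenesis genes 1 rose and 18 fell, 1 and 25 adjusted over the list alone (median -0.30, camera adjusted p = 4.92e-05, adjusted p = 0.674 with an estimated correlation), with nop56 at 191 ± 9.43 against 309.7 ± 37.5 FPKM. Among cohesin subunits and regulators with ctcf, 1 of 15 rose and 6 fell, 3 and 6 adjusted over the list alone (camera adjusted p = 0.395). The acetyltransferase gene esco2 fell to 93.5 ± 5.71 against 135 ± 7.44 FPKM and the subunit gene stag2a rose to 27.0 ± 1.11 against 14.8 ± 3.07. Of 43 cell cycle genes 3 rose and 16 fell, 6 and 19 adjusted over the list alone, without a list call (median -0.25, camera adjusted p = 0.0791). This direction turned under quantile normalization, where the list lay 0.0987 above the median of all genes. The same normalization brought the medians to -0.102 for histones, -0.183 for ribosomal proteins and -0.179 for ribosome biogenesis. Relative to the median of all genes these were -0.0385, -0.119 and -0.115. The sum of FPKM was 940200 ± 142200 in Rad21 MO and 1164000 ± 48510 in WT libraries at this stage.

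limma called 3077 of 14902 genes in Rad21 MO embryos at 4.5 hpf, 1576 higher and 1501 lower, of which 649 and 111 changed at least 2-fold. Libraries did not overlap for 40.6% of genes, where chance gives 10%. Rescaling to 1e+06 raised the median of all genes from -0.071 to 0.19 and gave 1950 higher and 73 lower genes. It ended the calls of rpl3, nop56, blf, esco2 and pou5f1. Quantile normalization gave 1313 and 705 genes. Under both ptbp1a, cirbp, bmp7a, grhl1 and HIST2H2AB (2 of 30) stayed called. The count was 1191 without Rad21 MO replicate 0, 1302 without WT replicate 1, 1616 without Rad21 MO replicate 2 and 1804 without WT replicate 2. The calls of pou5f1 and sox19b, unlike those of the other genes named for this comparison apart from the targets, ended in some of these runs.

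**Figure D2:**
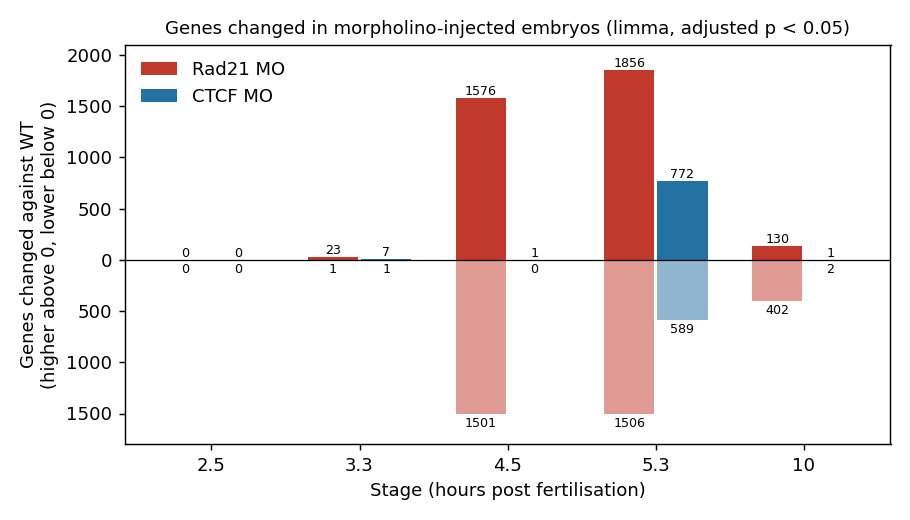
Number of genes (vertical axis) higher (above 0) or lower (below 0, paler) than WT by limma at adjusted p under 0.05 at each stage in hpf, for Rad21 MO and CTCF MO. Rad21 MO reaches 1576 higher and 1501 lower genes at 4.5 hpf and 1856 and 1506 at 5.3 hpf, CTCF MO 772 and 589 at 5.3 hpf. Rescaled to 1e+06 these splits become 1950 and 73, 3534 and 106, and 1680 and 88.

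At 5.3 hpf the excess of maternal transcripts in Rad21 MO embryos was again present. Levels of btg4 were 126 ± 51.2 FPKM against 14.4 ± 7.75 in WT (SD, n = 3; log2 change 3.07, SE 0.33, adjusted p = 0.000834) and those of mt2 254 ± 55.7 against 39.1 ± 8.38 (log2 change 2.67, SE 0.24, adjusted p = 0.000546). Those of buc were 125 ± 9.62 against 28.6 ± 5.71 (log2 change 2.102, SE 0.25, adjusted p = 0.00108) and those of dazl 96.0 ± 14.8 against 24.95 ± 2.18 (log2 change 1.89, SE 0.17, adjusted p = 0.000574). In the maternal class 593 of 1400 genes rose and 33 fell (median 0.55, camera adjusted p = 1.21e-22, adjusted p = 0.174 with an estimated correlation). Of 29 oocyte genes 10 rose and 3 fell, 14 and 4 adjusted over the list alone (median 0.39, camera adjusted p = 0.0101, adjusted p = 0.56 with an estimated correlation). Of 12 germline genes 6 rose and 2 fell, 7 and 2 adjusted over the list alone (median 0.78, camera adjusted p = 0.00366, adjusted p = 0.483 with an estimated correlation). The maternally supplied activator sox19b rose to 177 ± 8.33 against 80.1 ± 10.7 FPKM (log2 change 1.14, SE 0.11, adjusted p = 0.000612). A few zygotic genes were also higher. The gene cyp26a1 stood at 170 ± 34.9 against 78.6 ± 10.7 FPKM (log2 change 1.095, SE 0.15, adjusted p = 0.00154), and flh (chromosome 13, 14837120 to 14839117), needed for the notochord, at 252 ± 41.6 against 147 ± 28.0 (log2 change 0.78, SE 0.16, adjusted p = 0.00973).

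The genes that fell in Rad21 MO embryos at 5.3 hpf were led by ptbp1a at 26.4 ± 2.19 against 108 ± 19.9 FPKM (log2 change -1.98, SE 0.21, adjusted p = 0.000826) and cirbp at 817 ± 65.3 against 2294 ± 207 (log2 change -1.49, SE 0.15, adjusted p = 0.000689). In the zygotic class 23 of 2314 genes rose and 332 fell (median -0.27, camera adjusted p = 1.44e-09, adjusted p = 0.372 with an estimated correlation). Of 49 histone genes 32 fell and 0 rose, 40 adjusted over the list alone (median -0.53, camera adjusted p = 1.23e-12, adjusted p = 0.447 with an estimated correlation). Of 69 ribosomal protein genes 23 fell and 0 rose, 39 adjusted over the list alone (median -0.46, camera adjusted p = 1.86e-12, adjusted p = 0.569 with an estimated correlation). Of 58 ribosome biogenesis genes 23 fell and 0 rose, 29 adjusted over the list alone (median -0.37, camera adjusted p = 1.21e-09, adjusted p = 0.476 with an estimated correlation). Cell cycle genes were lower, 2 of 43 rising and 19 falling, 3 and 22 adjusted over the list alone (median -0.30, but 0.0018 above that of all genes under quantile normalization, camera adjusted p = 0.000106, adjusted p = 0.476 with an estimated correlation). The condensin gene smc4 stood at 89.0 ± 4.57 against 135 ± 4.55 FPKM and its partner ncapg at 80.6 against 127 FPKM. Of 20 enveloping layer genes 2 fell, the same number adjusted over the list alone (camera adjusted p = 0.0116, adjusted p = 0.698 with an estimated correlation). Of 4 mitochondrially encoded transcripts 2 fell, 3 adjusted over the list alone (median -0.45, a direction that turned under a scaling, camera adjusted p = 0.0453, adjusted p = 0.476 with an estimated correlation). In the cohesin list 2 of 15 rose and 7 fell, 3 and 8 adjusted over the list alone (camera adjusted p = 0.124). Under quantile normalization the medians were -0.0875 for histones, -0.0827 for ribosomal proteins and -0.225 for ribosome biogenesis, with that of all genes at -0.0491. Among 18 regulators of genome activation 2 rose and 6 fell, 2 and 7 adjusted over the list alone. The sum of FPKM was 1141000 ± 115500 in Rad21 MO, 1214000 ± 33690 in CTCF MO and 1460000 ± 76670 in WT libraries at 5.3 hpf.

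limma called 3362 of 15214 genes, 1856 higher and 1506 lower, 669 and 66 of them at least 2-fold. Libraries did not overlap for 41.2% of genes, where chance gives 10%. Rescaling to 1e+06 raised the median of all genes from -0.031 to 0.25 and gave 3534 higher and 106 lower. It ended the call of smc4, while ptbp1a, cirbp and ncapg stayed called. Without Rad21 MO replicate 1 the count was 1910, without WT replicate 0 2035, without Rad21 MO replicate 0 2124 and without Rad21 MO replicate 2 2231. The genes named here for 5.3 hpf, the targets included, kept their calls in these runs. Of the genes called at 5.3 hpf, 3346 were tested at 4.5 hpf, where 98.1% had the same sign and 2004 were also called.

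CTCF MO embryos at 4.5 hpf differed from WT in 1 of 14902 genes, with 2268 genes at an unadjusted p under 0.05 and 902 in the authors' deposited table made with Cuffdiff. This was the p53 target pmaip1 (chromosome 10, 8746744 to 8746979), a promoter of cell death, listed at 0 in all 3 WT and all 3 Rad21 MO libraries and at 14.2, 23.4 and 49.2 FPKM in CTCF MO libraries (adjusted p = 0.00308). Its call ended in the fit of all 45 libraries. Of 29 p53 targets 1 rose, 5 adjusted over the list alone (median 0.21, camera adjusted p = 0.0258, adjusted p = 0.971 with an estimated correlation). Also, 5 of 12 germline genes rose and 2 fell adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.0328, adjusted p = 0.971 with an estimated correlation). Maternal transcripts had a median log2 change of 0.15 with 0 of 1409 called (camera adjusted p = 2.16e-05, adjusted p = 0.385 with an estimated correlation). The count of called genes was 127 without CTCF MO replicate 1, 3 without WT replicate 2 and 0 without CTCF MO replicate 0. Without any 1 CTCF MO library pmaip1 no longer passed the filter of 3 libraries. Libraries did not overlap for 20.5% of genes, where chance gives 10%.

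Among the largest rises in CTCF MO embryos at 5.3 hpf were single genes with roles in stress responses and amino acid transport. The stress sensor sesn2 (chromosome 19, 45226142 to 45242485) stood at 34.2 ± 6.64 against 6.76 ± 1.46 FPKM in WT (SD, n = 3; log2 change 2.18, SE 0.20, adjusted p = 0.000786). The glutathione-degrading chac1 (chromosome 20, 28296498 to 28299069) stood at 176 ± 74.3 against 37.5 ± 2.82 (log2 change 2.09, SE 0.34, adjusted p = 0.00815) and the amino acid transporter slc1a4 (chromosome 13, 24655103 to 24671375) at 14.1 ± 8.02 against 1.25 ± 0.0736 (log2 change 2.56, SE 0.41, adjusted p = 0.00783). Of 23 heat and stress response genes 4 rose and 3 fell, 5 and 4 adjusted over the list alone, without a list call (camera adjusted p = 0.475). Those that rose included the mitochondrial chaperone hspe1 (chromosome 9, 33334324 to 33338315) at 90.5 ± 8.44 against 41.4 ± 5.85 FPKM and the stress transcription factor atf4b2 (chromosome 3, 24489174 to 24492060) at 29.4 ± 4.31 against 11.4 ± 1.63. Maternal and germline transcripts were higher too. Here dazl stood at 113 ± 27.3 against 24.95 ± 2.18 FPKM (log2 change 2.11, SE 0.17, adjusted p = 0.000586) and btg4 at 58.6 ± 4.36 against 14.4 ± 7.75 (log2 change 2.06, SE 0.33, adjusted p = 0.00811). Further, 5 of 12 germline genes rose and 0 fell, 7 and 2 adjusted over the list alone (median 0.67, camera adjusted p = 0.00142, adjusted p = 0.507 with an estimated correlation). In the maternal class 223 of 1400 genes rose and 26 fell (median 0.29, camera adjusted p = 1.71e-10, adjusted p = 0.174 with an estimated correlation). The oocyte growth factor gdf9 went the other way, falling to 3.42 ± 0.367 against 8.12 ± 0.679 FPKM (log2 change -1.05, SE 0.15, adjusted p = 0.00485). Of 29 oocyte genes 8 rose and 2 fell, 9 and 3 adjusted over the list alone, without a list call (camera adjusted p = 0.076).

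Genes that fell in CTCF MO embryos at 5.3 hpf included, beside ctcf, the transcription initiation factor taf13 (chromosome 23, 20717388 to 20718291) at 85.7 ± 7.87 against 178 ± 2.75 FPKM (log2 change -1.05, SE 0.091, adjusted p = 0.000649). Others were the signal recognition particle gene srp14 (chromosome 17, 1330428 to 1351974) at 65.2 ± 13.9 against 145 ± 20.9 (log2 change -1.16, SE 0.15, adjusted p = 0.00383) and the peroxiredoxin gene prdx1 (chromosome 2, 5748880 to 5758079) at 16.0 ± 6.87 against 47.1 ± 11.8 (log2 change -1.56, SE 0.28, adjusted p = 0.0125). The paraxial mesoderm list as a whole had a median of 0.19 without a list call (camera adjusted p = 0.659). Its members that fell, 2 of 17 over all genes (1 higher and 2 lower adjusted over the list alone), were the segmentation clock gene her7 (chromosome 5, 71711884 to 71713200) at 34.2 ± 3.57 against 60.0 ± 0.914 and tbx16 (chromosome 8, 54012018 to 54031716) at 177 ± 23.3 against 287 ± 8.29 FPKM. Of 58 ribosome biogenesis genes 10 fell and 0 rose, 22 adjusted over the list alone (median -0.27, camera adjusted p = 4.59e-09, adjusted p = 0.507 with an estimated correlation). Medians were also below 0 for ribosomal proteins (1 of 69 fell, 0 adjusted over the list alone, camera adjusted p = 3.63e-07) and histones (3 of 49 fell, 2 adjusted over the list alone, camera adjusted p = 4.21e-05). The same held for cell cycle genes (1 of 43 rose and 7 fell, 3 and 14 adjusted over the list alone, camera adjusted p = 0.0169) and mitochondrially encoded transcripts (0 of 4 called, 2 lower adjusted over the list alone, camera adjusted p = 0.0382). This direction turned under a scaling for each of these lists. Their adjusted p with an estimated correlation was 0.828, 0.507, 0.661 and 0.507. Of the cohesin list 1 of 15 rose and 5 fell, 2 and 6 adjusted over the list alone (camera adjusted p = 0.037, adjusted p = 0.507 with an estimated correlation). That list includes ctcf, the target itself, among those that fell, and was not tested without it. Of 20 enveloping layer genes 2 fell (camera adjusted p = 0.0307, adjusted p = 0.828 with an estimated correlation).

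In CTCF MO embryos at 5.3 hpf limma called 1361 of 15214 genes, 772 higher and 589 lower, 254 and 46 at least 2-fold. Libraries did not overlap for 27.9% of genes, where chance gives 10%. Rescaling to 1e+06 raised the median of all genes from 0.0022 to 0.215, gave 1680 higher and 88 lower and ended the calls of her7 and tbx16. The other genes named for this comparison, rad21a aside, stayed called under it. The count was 456 without CTCF MO replicate 1, 528 without WT replicate 0, 559 without CTCF MO replicate 0 and 656 without WT replicate 1. The calls of ctcf, sesn2, chac1, slc1a4, dazl, btg4, gdf9, hspe1, atf4b2, taf13, srp14, prdx1, her7 and tbx16 held in each of these runs. Of the called genes 1339 were tested at 4.5 hpf, where 96.0% had the same sign and 0 were called.

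**Figure D3:**
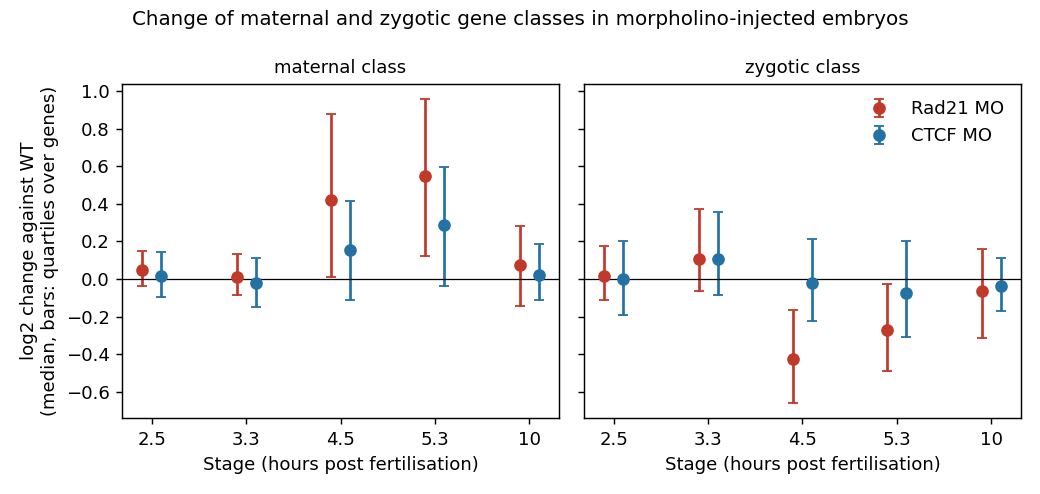
Median log2 change against WT (points, bars span the quartiles over genes) of the maternal and zygotic gene classes at each stage in hpf, for Rad21 MO and CTCF MO. In Rad21 MO the maternal class is at 0.42 and 0.55 and the zygotic class at -0.43 and -0.27 at 4.5 and 5.3 hpf. After rescaling to 1e+06 the zygotic medians of 5.3 hpf were 0.011 in Rad21 MO and 0.17 in CTCF MO (-0.073 before), below the medians of all genes, which rose to 0.254 and 0.215.

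By 10 hpf, at the end of gastrulation, paraxial mesoderm genes were lower as a group in Rad21 MO embryos, as were single genes of other kinds. The LIM homeobox gene lhx9 (chromosome 22, 24970014 to 24979988) stood at 0.955 ± 0.277 against 7.46 ± 0.846 FPKM in WT (SD, n = 3; log2 change -2.12, SE 0.24, adjusted p = 0.00473). The homeobox gene dlx4b (chromosome 12, 6057526 to 6066666) was at 2.57 ± 1.09 against 14.7 ± 3.09 (log2 change -2.16, SE 0.26, adjusted p = 0.00596) and the hyaluronan synthase gene has2 (chromosome 16, 17749944 to 17767770) at 2.83 ± 0.540 against 13.4 ± 2.79 (log2 change -1.90, SE 0.19, adjusted p = 0.00473). Likewise cyp26a1 was at 9.52 ± 4.35 against 37.5 ± 3.15 (log2 change -1.95, SE 0.24, adjusted p = 0.00687) and wnt3a (chromosome 2, 3599277 to 3652698) at 1.67 ± 0.494 against 6.88 ± 0.357 (log2 change -1.58, SE 0.21, adjusted p = 0.00833). Of 22 paraxial mesoderm genes 4 fell and 0 rose, 11 adjusted over the list alone (median -0.43, camera adjusted p = 2.16e-05, adjusted p = 0.0838 with an estimated correlation). Among them was the muscle regulator myod1 (chromosome 25, 32264523 to 32266764) at 36.01 ± 4.17 against 78.1 ± 8.25 FPKM (log2 change -1.10, SE 0.16, adjusted p = 0.0126). Early zygotic genes had a median of -0.21 with 1 of 52 higher and 5 lower, 2 and 9 adjusted over the list alone (camera adjusted p = 0.00229, adjusted p = 0.366 with an estimated correlation). Neural genes had one of -0.21 with 2 of 38 lower, 1 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.00555, adjusted p = 0.555 with an estimated correlation). FGF and Wnt genes had one of -0.21 with 1 of 21 lower, 2 adjusted over the list alone (camera adjusted p = 0.00855, adjusted p = 0.474 with an estimated correlation). None of 37 hox genes was called (median 0.011, which turned under a scaling, camera adjusted p = 0.71).

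Cell cycle, ribosome biogenesis and histone genes were lower as groups at 10 hpf in Rad21 MO embryos. Of 43 cell cycle genes 14 fell and 0 rose, 20 adjusted over the list alone, and 2 had a change above 0 (median -0.36, camera adjusted p = 1.21e-16, adjusted p = 0.0791 with an estimated correlation). The replicative helicase genes mcm4 (chromosome 24, 37031304 to 37056313) at 72.5 ± 4.08 against 164 ± 10.2 FPKM (log2 change -1.17, SE 0.089, adjusted p = 0.00139) and mcm3 at 18 ± 3.27 against 47.1 ± 2.76 (log2 change -1.35, SE 0.17, adjusted p = 0.00659) were among them. The cyclin gene ccnd2a (chromosome 25, 17331000 to 17595838), outside the list, fell to 8.87 ± 1.49 against 30.6 ± 2.48 (log2 change -1.69, SE 0.18, adjusted p = 0.00473). Of 58 ribosome biogenesis genes 16 fell and 0 rose, 38 adjusted over the list alone (median -0.44, camera adjusted p = 4.46e-20, adjusted p = 0.169 with an estimated correlation), with nop58 (chromosome 6, 8031309 to 8062529) at 223 ± 14.8 against 390.1 ± 19.99 FPKM. Of 49 histone genes 20 fell and 0 rose, 33 lower and 1 higher adjusted over the list alone (median -0.67, camera adjusted p = 2.97e-18, adjusted p = 0.0791 with an estimated correlation). Under quantile normalization the medians at this stage shrank to -0.235 for cell cycle, -0.278 for ribosome biogenesis and -0.338 for histone genes. Among ribosomal protein genes 0 of 70 were called, with a median of -0.11 that turned under a scaling (camera adjusted p = 0.0384, adjusted p = 0.908 with an estimated correlation). Of 15 genes linked to cohesin in earlier work 4 fell, 2 higher and 7 lower adjusted over the list alone (median -0.20, camera adjusted p = 0.0299, adjusted p = 0.169 with an estimated correlation), with the proto-oncogene myca at 2.103 ± 1.16 against 9.80 ± 1.01 FPKM.

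Among genes that rose at 10 hpf in Rad21 MO embryos were the p53 targets gadd45aa at 50.4 ± 11.8 against 8.09 ± 5.54 FPKM (log2 change 2.64, SE 0.52, adjusted p = 0.0341), bbc3 at 34.5 ± 9.62 against 5.23 ± 5.85 (log2 change 2.87, SE 0.58, adjusted p = 0.0367) and sesn3 at 328 ± 63.6 against 112 ± 50.8 (log2 change 1.62, SE 0.31, adjusted p = 0.0294). Of 31 p53 targets 3 rose and 4 fell, 14 and 5 adjusted over the list alone, and 23 had a change above 0 (median 0.68, camera adjusted p = 0.00085, adjusted p = 0.515 with an estimated correlation). Libraries of 1 group stood apart in these genes. The target ccng1 was at 1824, 441 and 339 FPKM in WT replicates 0, 1 and 2, at 2029, 2258 and 2074 in Rad21 MO and at 1396, 361 and 1702 in CTCF MO libraries. Over all genes limma called 532 of 16485, 130 higher and 402 lower, 62 and 119 at least 2-fold. Libraries did not overlap for 26.3% of genes, where chance gives 10%. Counts were 89 under rescaling to 1e+06 (16 higher, 73 lower) and 312 under quantile normalization (78 and 234). The count was 62 without WT replicate 2, 64 without Rad21 MO replicate 2, 78 without WT replicate 1, 87 without Rad21 MO replicate 1 and 232 without Rad21 MO replicate 0. Of the genes named for this comparison, the calls of gadd45aa, bbc3 and sesn3 ended in each of these runs and under rescaling to 1e+06. Those of myod1 and myca ended without WT or Rad21 MO replicate 2, and that of myod1 also under rescaling, while lhx9, dlx4b, has2, cyp26a1, wnt3a, mcm3, mcm4, ccnd2a and nop58 stayed called.

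**Figure D4:**
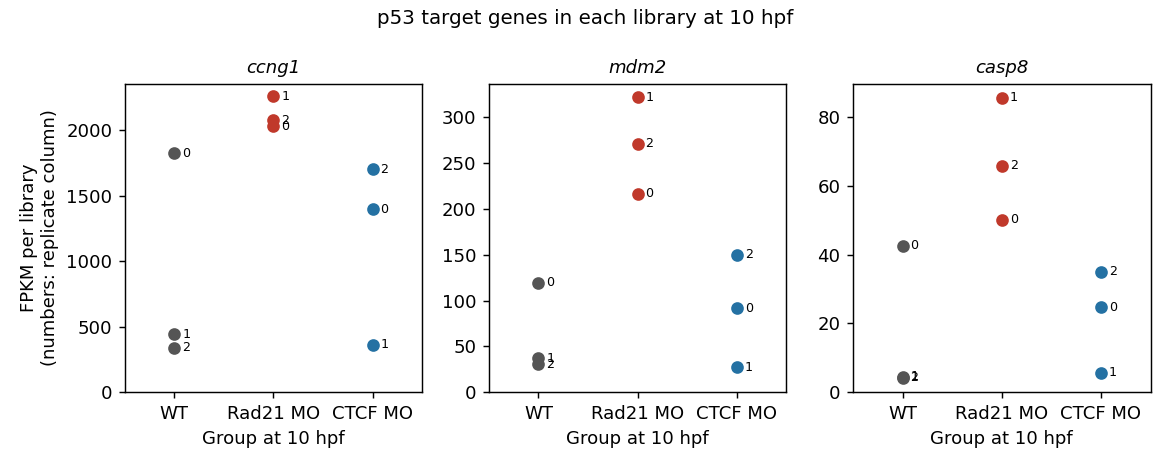
FPKM (vertical axes) of the p53 targets ccng1, mdm2 and casp8 in each library at 10 hpf (points, numbered by replicate column) for WT, Rad21 MO and CTCF MO. The 3 Rad21 MO libraries lie at 2029 to 2258 FPKM for ccng1, while WT replicate 0 (1824) and CTCF MO replicates 0 and 2 (1396 and 1702) stand apart from the other libraries of their groups (339 to 441).

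CTCF MO embryos at 10 hpf differed from WT in 3 of 16485 genes, with 641 at an unadjusted p under 0.05 and 135 in the authors' deposited table. Libraries did not overlap for 7.40% of genes, where chance gives 10%. All 3 hold libraries listed at 0 and were named after their values were seen. A copy of the spliceosomal RNA U1 (chromosome 12, 2887553 to 2887717) was at 9.26, 8.70 and 10.4 FPKM in WT and at 0 in CTCF MO and Rad21 MO libraries. The kinase inhibitor gene camk2n2 (chromosome 24, 25964945 to 25965724) was at 2.62, 4.80 and 2.84 in WT and at 0 in both knockdowns. SNORD100 (chromosome 23, 31665071 to 31675103) was listed at 0 in WT and Rad21 MO libraries and at 4021, 4566 and 5592 in CTCF MO libraries. Without WT replicate 1 or 2 or CTCF MO replicate 0 or 2, 1 gene was called. No member of any list was called. The median was -0.10 for ribosome biogenesis (camera adjusted p = 0.00163, adjusted p = 0.918 with an estimated correlation), -0.080 for ribosomal proteins (camera adjusted p = 0.0216, adjusted p = 0.922 with an estimated correlation) and -0.063 for cell cycle genes (camera adjusted p = 0.0434, adjusted p = 0.918 with an estimated correlation).

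The remaining lists are given in short. In Rad21 MO embryos at 4.5 hpf limma called 3077 of 14902 genes. Of 24 Nodal and mesendoderm and 13 paraxial mesoderm genes 0 were called there, also adjusted over the list alone. Of 20 BMP and ventral genes 1 rose and 4 fell (1 and 7 adjusted over the list alone), and 0 of 10 yolk syncytial layer genes rose and 1 fell (the same adjusted over the list alone). Of 29 p53 targets 4 rose and 6 fell (6 and 6 adjusted over the list alone). Of 21 heat and stress response genes 2 rose and 5 fell (3 and 7 adjusted over the list alone), and neither list was called there. Clustered protocadherins were measured for 1 to 3 genes of 43 per stage, of which pcdh1g30 fell in Rad21 MO embryos at 10 hpf to 3.48 ± 0.278 against 6.90 ± 0.560 FPKM (adjusted p = 0.0271). This call ended without any of 5 libraries left out in turn and under rescaling to 1e+06. Of 53 miR-430 copies at most 1 passed the filter, and it was not called over all genes. Markers of ovarian somatic cells (3 or 4 measured) and of tissues of later stages (2 to 10 measured) gave 0 calls by limma in Rad21 MO and CTCF MO embryos at 4.5, 5.3 and 10 hpf, also adjusted over the list alone. At 4.5 hpf the median of the later tissue markers was nevertheless 0.32 in Rad21 MO and 0.29 in CTCF MO embryos, and that of the ovarian markers 0.063 and 0.061.

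Both knockdowns were then compared with each other. limma found 0 of 13595 genes different at 2.5 hpf (766 at an unadjusted p under 0.05), and 6 at 3.3 hpf (4 higher and 2 lower in Rad21 MO). It called 411 at 4.5 hpf (225 and 186), 684 at 5.3 hpf (418 and 266) and 558 at 10 hpf (139 and 419). At 5.3 hpf ctcf stood at 329 ± 4.80 FPKM in Rad21 MO and 237 ± 3.39 in CTCF MO embryos (log2 difference 0.47, SE 0.077, adjusted p = 0.0186). At 10 hpf it was at 96.0 ± 7.92 and 155 ± 13.1 (log2 difference -0.69, SE 0.10, adjusted p = 0.0138). Both calls ended without single libraries of either group, and at 10 hpf also under rescaling to 1e+06. That rescaling gave 132 higher and 14 lower at 4.5 hpf, with the median of all genes at 0.18 (-0.043 before), 386 and 102 at 5.3 hpf, and 1 and 2 at 3.3 hpf. At 4.5 hpf 0 genes were called without CTCF MO replicate 1 or 2, 1 without Rad21 MO replicate 2, 4 without Rad21 MO replicate 1 and 8 without Rad21 MO replicate 0. At 5.3 hpf the count was 62, 68 and 63 without Rad21 MO replicate 0, 1 and 2 and 191, 114 and 314 without CTCF MO replicate 0, 1 and 2. At 10 hpf it was 185, 76 and 57 without Rad21 MO replicate 0, 1 and 2 and 114, 295 and 167 without CTCF MO replicate 0, 1 and 2. At 3.3 hpf it was 0 without Rad21 MO replicate 2, 1 without CTCF MO replicate 0 or 2 and 3 without Rad21 MO replicate 0.

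Calls of both knockdowns overlapped at 5.3 hpf, where dazl, btg4 and sox19b rose in each. Of the genes tested, 590 rose in both, against 94.2 for independent lists, 374 fell in both, against 58.3, and 6 moved in opposite directions. Simulated groups without effect that share the WT libraries gave 0. Such groups yield almost no calls, so this does not measure how much the shared libraries add to the overlap. The numbers for independent lists leave the sharing out as well. Fold changes had a covariance across genes of 0.172 at 5.3 hpf against 0.058 in the simulation, and r of 0.625 against 0.495. At 4.5 hpf the covariance was 0.131 against 0.060, at 3.3 hpf 0.060 against 0.048, at 2.5 hpf 0.055 against 0.046 and at 10 hpf 0.061 against 0.063. Genes are not independent replicates, and with 3 WT libraries per stage the controls could not be split, so part of the excess may come from the shared controls.

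Differences of an effect between adjacent stages were tested in the fit of all 45 libraries. Between 3.3 and 4.5 hpf the Rad21 MO effect differed for 2203 of 18943 genes (1067 higher, 1136 lower at the later stage), and between 5.3 and 10 hpf for 2671 (947 and 1724). The CTCF MO effect differed for 20 genes between 3.3 and 4.5 hpf and for 838 between 5.3 and 10 hpf (279 and 559). Rescaled to 1e+06, the Rad21 MO splits became 1625 and 204 and 181 and 2468, with the median of all genes at 0.12 and -0.205 (-0.043 and 0.027 before). The CTCF MO split between 5.3 and 10 hpf became 39 and 468, with a median of -0.14 (-0.002 before).

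Projected on the WT course, Rad21 MO libraries at 4.5 hpf lay at 0.458 ± 0.060 (SD, n = 3) between WT of 3.3 hpf (0) and 5.3 hpf (1), over 5965 genes. There WT lay at 0.7 ± 0.0745 and CTCF MO at 0.639 ± 0.0896. The exact permutation p was 0.1, the smallest possible, for Rad21 MO and 0.5 for CTCF MO (adjusted p = 0.3 and 0.6). Over genes that fall in WT, positions were 0.260 ± 0.0702 in Rad21 MO, 0.498 ± 0.113 in CTCF MO and 0.680 ± 0.0691 in WT libraries. Over genes that rise they were 0.533 ± 0.0586, 0.692 ± 0.0817 and 0.708 ± 0.0768. At 3.3 hpf positions between WT of 2.5 and 4.5 hpf were 0.301 ± 0.0445 for Rad21 MO, 0.286 ± 0.0134 for CTCF MO and 0.239 ± 0.0272 for WT (exact permutation p = 0.2 and 0.1, adjusted p = 0.4 and 0.3). At 5.3 hpf positions between WT of 4.5 and 10 hpf were 0.101 ± 0.0143, 0.145 ± 0.0256 and 0.131 ± 0.0367 (exact permutation p = 0.4 and 0.7).

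**Figure D5:**
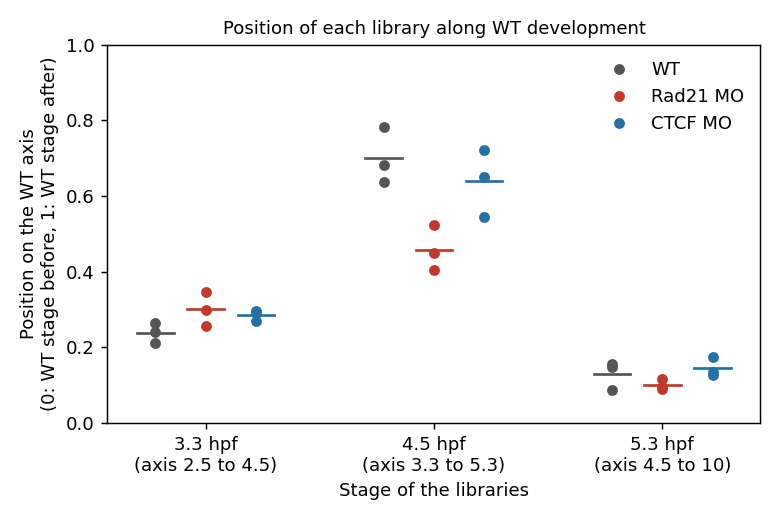
Position of each library (points, lines are group means) on the line from WT of the stage before (0) to WT of the stage after (1) on the vertical axis, for libraries of 3.3, 4.5 and 5.3 hpf of WT, Rad21 MO and CTCF MO. At 4.5 hpf the Rad21 MO libraries lie at 0.404 to 0.523, below the WT libraries at 0.637 to 0.782.

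The authors' deposited table of Rad21 MO against WT lists 70, 326, 3668, 3525 and 1496 genes at the 5 stages from 2.5 to 10 hpf. Of the genes in the authors' deposited table, 0, 17, 2352, 2696 and 475 were also called here with the same sign. For CTCF MO the authors' deposited table lists 164, 89, 902, 2172 and 135 genes, of which 0, 3, 0, 1146 and 0 were also called here with the same sign. At 4.5 hpf the authors' deposited table splits the Rad21 MO genes into 2382 higher and 1286 lower.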

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

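Of the tests in this part, the splits of libraries, the delay as the cause of all changes and the search for a misplaced library were set before their results were seen. The tests on scaling, on the developmental point of the maternal and zygotic classes, on p53 targets and on early zygotic genes, and the sorting of splits by the groups they keep, were chosen only after the result was seen.

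A test of the difference itself showed effects that change between adjacent stages. The Rad21 MO effect differed between 2.5 and 3.3 hpf for 1 gene, between 3.3 and 4.5 hpf for 2203, between 4.5 and 5.3 hpf for 15 and between 5.3 and 10 hpf for 2671, and the CTCF MO effect for 1, 20, 2 and 838 genes. Simulated data without any effect gave up to 5, 7, 23 and 61 genes for Rad21 MO and up to 7, 9, 26 and 56 for CTCF MO. Of 100 drawn splits of the libraries within both stages, the real one included, 4 gave as many genes as the Rad21 MO effect between 5.3 and 10 hpf (highest other 4321). The other 3 keep the groups of 1 stage, and splits that mix both stages gave up to 54. This argues against chance there but does not exclude it, since the share is not adjusted for the number of differences tested. Between 3.3 and 4.5 hpf 9 splits gave as many for Rad21 MO (highest other 3019) and 11 for CTCF MO (368), and between 5.3 and 10 hpf 13 for CTCF MO (1886). These shares decide nothing. Of the splits that gave as many, 8, 10 and 10 keep the groups of 1 stage and so its whole effect, and splits that mix the libraries of both stages gave up to 7, 4 and 868 genes. For Rad21 MO from 2.5 to 3.3 and from 4.5 to 5.3 hpf 20 and 27 splits gave as many (highest others 107 and 6841), and for CTCF MO 28 and 73 (16 and 2979). Of the splits that mix both stages 14, 5, 22 and 54 gave as many. Their highest counts were 107 and 268 for Rad21 MO and 16 and 1389 for CTCF MO. Mixed splits can hold part of the knockdown effect, so chance is not excluded and sample structure not shown.

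For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real Rad21 MO counts of 0, 24, 3077, 3362 and 532 genes from 2.5 to 10 hpf were reached by 10, 1, 1, 1 and 1 of the 10 splits, with highest other counts of 13, 4, 2, 3 and 3. For CTCF MO the counts of 0, 8, 1, 1361 and 3 were reached by 10, 1, 8, 1 and 2 splits, with highest others of 4, 4, 6, 3 and 951. Between the knockdowns 0, 6, 411, 684 and 558 genes were reached by 10, 1, 1, 1 and 1 splits, with highest others of 1, 2, 3, 3 and 4. For the WT steps 428, 8119, 4242 and 11988 genes were reached by 1 split each, with highest others of 2, 1, 5 and 1. The split with 951 genes at 10 hpf, which points to a structure of the samples, sets WT replicate 0 with CTCF MO replicates 0 and 2 against WT replicates 1 and 2 with CTCF MO replicate 1.

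The maternal class was higher and the zygotic class lower in Rad21 MO embryos at 4.5 and 5.3 hpf. The tables argue against scaling as the whole cause, since the zygotic minus maternal difference under quantile normalization stayed at -0.759 (SD of 9 library pairs 0.306) and -0.658 (SD 0.206), and against a 3.3 hpf library under a 4.5 hpf name, since the lowest 4.5 hpf library lay 0.266 above the highest 3.3 hpf one on the WT axis. They also argue, on deposited values, against a delay as the cause of all changes. On the same side of WT at 3.3, 4.5 and 5.3 hpf lay 54 genes at 4.5 hpf and 235 at 5.3 hpf (highest other splits 1 and 5). Of these 40 and 149 lay below WT and 14 and 86 above. Lower calls depend on the scaling, and no other was tried. Only 1.14% and 4.25% of called genes lay so, and WT was not sampled in between. WT of 2.5 and 10 hpf was left out, and some of these genes lie within its levels. An earlier point of WT development as the source of most of the shift stays open. The falling genes put Rad21 MO libraries below WT by -0.419 and -0.0566, and the rising genes at 4.5 hpf put them nearer to WT. Called genes that differ in WT between the stages before and after moved towards the earlier one in 99.2% at 4.5 hpf. At 5.3 hpf it was only 57.4%. The embryos were staged by eye. A lack of cohesin that slows the embryo and one that acts on these transcripts cannot be told apart. The bound for this test was replaced after the result was seen. The first one (Rad21 MO within 1 SD of WT in rising or falling genes) would have argued against an earlier point at 5.3 hpf, with rising genes at 0.117 ± 0.0147 against 0.134 ± 0.0384. That axis runs to 10 hpf, and whether a short delay would show on it in the rising genes was not tested.

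The p53 targets lay higher in Rad21 MO embryos at 10 hpf, with a list level of 0.720, 1.11 and 0.913 per library against 0.558, -0.230 and -0.327 in WT and 0.461, -0.438 and 0.568 in CTCF MO libraries. The tables argue against scaling, since the list median stayed 0.675 above that of all genes under quantile normalization. A response to injection of the same size in both knockdowns stays open at 10 hpf: the Rad21 MO mean exceeded the CTCF MO mean by 0.718 (0.915 ± 0.196 against 0.197 ± 0.553), less than the sum of both SDs. At 4.5 hpf the CTCF MO mean lay 0.445 above the Rad21 MO mean (0.436 ± 0.206 against -0.0089 ± 0.0456), more than that sum. This goes against such an equal response but does not settle it. Part of the gap comes from the list member pmaip1, which passed the filter only through the CTCF MO libraries. It was listed at 0 in the WT and Rad21 MO libraries, and the gap without it was not computed. Damage that follows from a lack of cohesin stays open as untested, and WT replicate 0, near CTCF MO replicates 0 and 2 and below all Rad21 MO libraries, has no label that sets it apart.

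Early zygotic genes lay above WT in both knockdowns at 3.3 hpf, 42 of 48 in both. The list level of the 6 knockdown libraries lay 0.618 above that of WT, more than the sum of both SDs (0.158 and 0.173). The lowest of them (0.491) lay above the highest WT library (0.142). These are the same libraries and genes in which the rise was found, so this is no separate test of chance values of the 3 WT libraries. The list calls also ended with an estimated correlation, so such values stay open. Something else that the 3 WT libraries share stays open, since no second control was at hand and both knockdowns differed by a median of 0.158 only, with 1 gene called between them. A slightly later point of WT development also stays open, with CTCF MO libraries 0.0475 above WT on the WT axis, more than the sum of both SDs, and Rad21 MO libraries 0.0619 above it, less than that sum. An effect of either protein on these genes before the bulk of genome activation stays open as untested.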

How the results depend on the processing

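Calls that rest on rescaling, a single library, the correlation between genes, the fit or the fold threshold are among the limits. FPKM without read totals leaves the scaling unsettled, and depth could not be set per gene. A gene count was taken as the same within 1.5 times, and a position if it moved by less than the SD between libraries. A class median was taken as the same if its call status held and, where called, its side, so its size could still shift. By these rules a pseudocount of 0.1 left 46 of 53 results the same, no filter 43, rescaling to 1e+06 35, quantile normalization 42 and the block 43. The fit of all 45 libraries left 6 of 19, the 2-fold threshold 9 of 27 and leaving out libraries 246 of 366 values. Of 374 named results, 363, 325, 224, 282, 332 and 340 kept their call under the first 6 of these. Further, 1653 runs without a library kept a named call while 570 lost one. The cause was not tested unless given. A block by the titles' replicate letter and stages by the age label were planned and not run, because the columns carry no letter. The block by column number, the exchanges and the paired removals were chosen after seeing the data.

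Counts at least 2-fold, which drop genes by construction, were 10, 760, 735 and 181 for Rad21 MO from 3.3 to 10 hpf, 300 for CTCF MO at 5.3 hpf, and 3, 160, 173 and 182 between the knockdowns from 3.3 to 10 hpf. They were 3598, 886 and 7532 for the last 3 WT steps, 793, 7 and 1046 for the stage differences of Rad21 MO from 3.3 hpf and 13, 0 and 314 for those of CTCF MO. Rescaling to 1e+06 gave 9, 2023 and 89 genes for Rad21 MO at 3.3, 4.5 and 10 hpf, 2 for CTCF MO at 4.5 hpf, and 3, 146 and 156 between the knockdowns at 3.3, 4.5 and 10 hpf. It gave 0 for the Rad21 MO stage differences up to 3.3 and from 4.5 to 5.3 hpf, and 2, 1, 1 and 507 for those of CTCF MO. It brought the zygotic median of Rad21 MO at 2.5 hpf to 0.147 and the maternal one of CTCF MO to 0.101, both then past the threshold. It put the zygotic medians at 5.3 hpf at 0.0109 in Rad21 MO and 0.167 in CTCF MO, still below the medians of all genes, which it raised to 0.254 and 0.215, so the change of sign is that common shift. It moved the Rad21 MO position at 5.3 hpf to -0.0633 from WT. In Rad21 MO at 5.3 hpf cdh1 turned to 0.0117 and foxh1 to 0.0445, and ctcf in WT from 4.5 to 5.3 hpf to -0.00661. Quantile normalization gave 17 genes for CTCF MO at 3.3 hpf, 2018 and 312 for Rad21 MO at 4.5 and 10 hpf, and 337 between the knockdowns at 10 hpf. It gave 1451 for the Rad21 MO difference between 3.3 and 4.5 hpf and 2, 3, 4 and 481 for CTCF MO. Under it the zygotic medians of CTCF MO at 5.3 hpf (-0.0446) and Rad21 MO at 10 hpf (-0.0399) lost their calls. It turned cdh1 to 0.0856 and 0.011 in Rad21 MO at 4.5 and 5.3 hpf, apoeb to 0.0239 at 5.3 hpf, nanog in WT from 3.3 to 4.5 hpf to -0.171 and ctcf from 4.5 to 5.3 hpf to -0.0886.

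With an estimated correlation 0 of 65 list calls and 0 of 11 class calls remained. The fry test called 28 lists. The fit of all 45 libraries, which pools the spread over stages, gave 1, 105, 4729 and 2079 genes for Rad21 MO at 2.5, 3.3, 4.5 and 10 hpf, and 1, 33, 960, 2489 and 76 for CTCF MO. It gave 25, 2215, 1762 and 2230 between the knockdowns at 2.5, 4.5, 5.3 and 10 hpf. No filter, which adds genes near the floor, gave 7 and 325 for Rad21 MO at 3.3 and 10 hpf, 3 and 5 for CTCF MO at 4.5 and 10 hpf, 77, 340 and 336 between the knockdowns from 4.5 hpf. It gave 0 for Rad21 MO from 2.5 to 3.3 hpf, 6 for CTCF MO from 4.5 to 5.3 hpf, and a zygotic median of -0.0146 for CTCF MO at 5.3 hpf that lost its call. A pseudocount of 0.1 gave 643 WT genes from 2.5 to 3.3 hpf, 0 and 11 for the first stage differences, a CTCF MO position at 3.3 hpf of 0.0693 from WT. It ended the calls of the maternal median of Rad21 MO at 2.5 hpf (0.0403) and the zygotic ones of CTCF MO at 5.3 hpf (-0.0777) and Rad21 MO at 10 hpf (-0.0461).

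With the column number as a replicate block, counts were 5 and 248 for Rad21 MO at 3.3 and 10 hpf, 58 for CTCF MO at 4.5 hpf, 923, 344 and 262 between the knockdowns from 4.5 hpf. They were 0 for the Rad21 MO difference from 2.5 to 3.3 hpf, 31 and 5 for CTCF MO from 3.3 and 4.5 hpf. In this block the zygotic median of CTCF MO at 5.3 hpf (-0.0729) lost its call. Over all stages the numbers are not shown to pair the libraries. Only 11 of 45 same-numbered pairs had r over 0.1 (-0.192 to 0.366), and 18 of 45 fitted best with their own number. Hints of pairing are limited to single stages. At 5.3 hpf all 3 pairs of WT and Rad21 MO fitted best with their own number (r of 0.255, 0.295 and 0.206), where the block gave 2952 genes. At 4.5 hpf the positions rank 0, 2, 1 in WT, Rad21 MO and CTCF MO alike, with CTCF MO below WT at each number.

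Exchanging 1 Rad21 MO library of 3.3 hpf with 1 of 4.5 hpf (9 pairs) gave as few as 3 genes for Rad21 MO at 3.3 hpf, 2 between the knockdowns at 3.3 hpf and 5 to 1054 at 4.5 hpf. The exchange gave 0 for the stage difference from 2.5 to 3.3 hpf, 3901 to 5600 from 3.3 to 4.5 hpf and as many as 32 from 4.5 to 5.3 hpf. It turned the maternal median at 3.3 hpf from 0.0082 to -0.136 to -0.0669 and moved positions to 0.17 to 0.245 (3.3 hpf) and -0.406 to -0.347 (4.5 hpf) from WT. Leaving out 1 of each gave 0 to 15, as few as 855 and as few as 0 for these stage differences.

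Leaving out single libraries gave 0 to 1, 2 to 19, 1191 to 2479, 1910 to 3355 and 62 to 562 genes for Rad21 MO from 2.5 to 10 hpf and 0 to 5, 4 to 21, 0 to 127, 456 to 1534 and 1 to 2 for CTCF MO. It gave 0 to 3, 0 to 8, 0 to 434, 62 to 314 and 57 to 295 between the knockdowns, and 2564 to 4566 in WT from 4.5 to 5.3 hpf. Stage differences ranged over 0 to 9, 1278 to 2433 and 0 to 75 for Rad21 MO up to 5.3 hpf and over 0 to 11, 0 to 177, 1 to 37 and 552 to 966 for CTCF MO. The maternal median of Rad21 MO at 2.5 hpf ranged from 0.0323 to 0.0497, and the zygotic ones of CTCF MO from -0.116 to 0.089 at 4.5 hpf (0.089 without CTCF MO replicate 0), -0.175 to -0.0204 at 5.3 hpf and -0.0622 to 0.00285 at 10 hpf.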

Other observations

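Cell cycle genes moved in both directions in Rad21 MO embryos at 4.5 hpf. The mitotic kinesin gene kif11 rose to 103 against 56.9 FPKM in WT and the replication factor gene cdc45 to 39.1 against 16.4. The cyclin gene ccne2 fell to 42.4 ± 5.33 against 108 ± 24.1 and the helicase gene mcm6 to 9.86 ± 3.85 against 28.4 ± 8.58 (SD, n = 3, limma log2 changes 0.85, 1.198, -1.31 and -1.46). Members of the p53 list parted likewise. The p53 inhibitor gene mdm4 rose to 24.2 ± 3.42 against 7.68 ± 0.706, while ccng1 fell to 417 against 641 (log2 changes 1.53 and -0.62). The call of ccng1 ended under rescaling to 1e+06. The stress gene sesn2, which rose in CTCF MO embryos at 5.3 hpf, also rose in Rad21 MO embryos at that stage, to 17.8 against 6.76 FPKM (log2 change 1.28).

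Some transcripts in Rad21 MO embryos lay outside the WT levels of 3.3, 4.5 and 5.3 hpf alike (adjusted p under 0.05 against each), here named after their values were seen. At 5.3 hpf cyp26a1 stood at 170 FPKM against WT means of 27.7, 85.2 and 78.6, and at 4.5 hpf gid8a at 47.5 ± 1.57 against 27.5, 17.3 and 24.3. Below all of these stages lay nme2b.2, at 321 ± 62.7 at 4.5 hpf against 624, 643 and 542, and the RNA exosome gene exosc10, at 54.0 ± 3.21 against 69.2, 87.2 and 93.5. So did, at 5.3 hpf, the chaperone gene hsp90b1, at 74.6 ± 13.0 against 267, 164 and 147. WT of 10 hpf, outside this comparison, was at 36.2 FPKM for hsp90b1 and 54.3 for exosc10. The values named for cyp26a1, gid8a and nme2b.2 lay beyond the WT means of 2.5 and 10 hpf too. In CTCF MO embryos 16 genes lay outside this range at 4.5 hpf and 432 at 5.3 hpf, 256 above and 176 below.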
